A study of Caenorhabditis elegans with 19 samples.

How the data were processed

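Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans larvae that carried LIN-14, a transcription factor of developmental timing, fused to GFP at its C terminus. Per the labels' protocols, larvae were collected 8 ± 1 hours after plating on food for the first larval stage (L1) and 21 ± 1 hours for the second (L2), and chromatin was pulled down with beads that bind GFP. The labels list 19 libraries. These are 5 ChIP and 4 input libraries of L1, 5 ChIP and 4 input libraries of L2, and 1 ChIP library of L1 larvae of the N2 strain, which has no GFP tag. The libraries served as replicates only inside the authors' own steps, and the N2 library is not analysed here. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure the spread between libraries, which may be technical.

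Per the submitters' processing notes, BWA, SAMtools, MACS2, DiffBind and ChIPseeker were used. Versions, the genome build and the normalization are not given in the sources used here. Per the peak names in the files, the libraries of a stage were merged and outliers were left out before peaks were called, so each stage has 1 list and no value per library. Read depth per library is therefore unknown. In the deposited peak lists each peak has a score, which equals 10 times the -log10 q cut to a whole number, a fold enrichment ratio over control at its summit, and a -log10 q-value. The score, the fold enrichment and the -log10 q-value are the authors', and were used to describe, rank and filter peaks within 1 list. The authors' deposited table of the comparison gives, per the file headers, log2 mean concentrations (normalised read counts) over both stages, in L2 and in L1, their log2 fold, and a p-value with its false discovery rate (FDR). The log2 fold equals L2 minus L1, so a negative value is lower occupancy in L2. Sites with an FDR above 0.3 are not listed in that table. The relation between p and FDR puts the number of tested sites at about 16902, of which 14675 are listed. From sites with clear folds, the mean concentration gave L1 a weight of 0.500 ± 0.005 (SD over 2193 sites), which is what equal numbers of libraries per stage give.

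Gene names, site classes and distances to transcript starts were taken from the authors' annotated tables, which assign each site to its nearest transcript. The promoter classes count distance to either side of the transcript start. Symbols and biotypes came from a RefSeq gene table of assembly WBcel235 (46926 genes), to which 99.8% of L1 peaks, 99.9% of L2 peaks and 99.8% of the compared sites were matched. Transcript starts in the files equal those of WBcel235 for 1.95% of 18449 transcripts assigned to L1 peaks, so no coordinate of that table is printed. All positions are those of the files, counted from 1, in a genome build that is not given in the sources used here. The annotated tables hold 12 fewer L1 peaks and 3 fewer L2 peaks than the peak lists. These are the first peak of each list and the peaks on the mitochondrial chromosome.

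Peaks of both stages were compared by an overlap of at least 1 bp (bedtools 2.31.1), and chance overlap came from 100 shuffles of the L2 peaks within chromosomes. Shares have 95% Wilson intervals, which cover counting error over peaks. Sites with an FDR below 0.05 in the authors' deposited table were counted as changed. Two-sided Fisher's exact tests compared the shares of changed sites between site classes and between the X chromosome and autosomes. Sites and genes are not replicates, and these p-values describe the lists. For each of 23 gene lists, a two-sided Fisher's exact test set members with a peak against all other annotated genes, and members with a lowered or raised site against other genes with a listed site, using for each gene the site with the highest concentration. Benjamini-Hochberg adjustment was made over the lists, within each direction. A permutation test set each list's median log2 fold against 10000 random gene sets matched in 20 concentration bins. Counts adjusted over the list alone apply Benjamini-Hochberg to the deposited p-values of the members with a listed site. Sites with an FDR above 0.3 are missing, so these p-values were already selected as small. Such counts can therefore be too high, and they do not hold the FDR at 0.05. The overlap of raised sites with peaks was set against 10000 random sets of other listed sites, drawn from the 50 with the nearest concentration in the same stage. Each site was also tested against the median log2 fold in place of 0, with a standard error derived from its deposited fold and p. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

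The tests were tried on simulated data. With 15 percentage points added to the lowered share of the chemoreceptors, the list test recovered them in 100% of 40 runs over 10006 genes. With 20 points added to the collagens it recovered them in 70.0%, and false calls stayed at or below 0.114%. Among 14675 simulated sites with the standard errors of the real table, the test against the median recovered 91.5% of 200 sites moved by -1.00 and 4.50% of those moved by -0.50, so it has little power for departures of that smaller size. The simulated folds varied by the full standard error, independently between sites, which is more than the listed real folds vary. These shares may therefore not hold for the real table.

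The gene lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. Named are the genes of the 10 peaks with the highest fold enrichment of each stage, those of the 10 lowered and 10 raised sites with the lowest FDR at 1 site per gene, up to 3 members of each list with the lowest FDR below 0.05 with the member of highest concentration, and 16 genes of developmental timing and neuronal maturation whatever their values. Not every gene that this rule names is printed, and 1 lowered site is not reported here. The alternatives were stricter thresholds, merged peaks, other overlap rules, other choices of site per gene, other gene backgrounds and recentred folds. A search for the LIN-14 motif at peak centres needs a genome sequence and was not run. Tests that leave out or regroup libraries need values per library and were not run.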

Results

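LIN-14 is a nuclear factor that sets the timing of early larval development in Caenorhabditis elegans, and its level is known to fall after the first larval stage. Its genomic occupancy was profiled by ChIP-seq of a LIN-14::GFP fusion in whole larvae of the L1 stage (5 ChIP and 4 input libraries) and of the L2 stage (5 ChIP and 4 input libraries). The processed data comprised 1 peak list per stage, called on merged libraries, and 1 comparison of the stages. Because no values per library were at hand, depth per library is unknown and peak values carry no replicate error. Peak enrichment values are those of the authors' peak caller, and which libraries served as its control is not given in the sources used here.

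The first question was where LIN-14 was bound in L1. Peaks were assigned to most protein-coding genes, mainly close to transcript starts. The untagged N2 library was not used here to set aside sites that appear without the tag. The strongest lay at the start of the non-coding RNA gene F19G12.12 (chromosome X, 1408793 to 1410443), with a fold enrichment over control of 3.57. The next lay within 1 kb of the start of eat-2, which encodes a nicotinic acetylcholine receptor subunit of the pharynx (chromosome II, 14170035 to 14171063), with a fold enrichment of 3.4. Among the other 8 of the top 10 genes were the non-coding T28D6.10 (3.39), Y69H2.26 (3.22), Y22D7AR.19 (3.19) and 2RSSE.6 (3.22), the last with its peak in exon 9 of ccep-290. The protein-coding srlf-20 (3.31), Y5H2A.4 (3.22), F40E12.1 (3.21) and wdr-31 (3.19) made up the rest. The L1 list held 37030 peaks with a median width of 292 bp, which covered 13.6 Mb. Most were weak, with a median fold enrichment of 1.81 and 24.7% at 2 or more. Promoters within 1 kb of a transcript start held 56.0% of annotated peaks (95% Wilson interval 55.5 to 56.5), all promoter classes together 89.1%, exons 6.57% and introns 1.65%. The share of the genome in each class was not computed, so neither these shares nor those of L2 below show a preference for promoters. Peaks were assigned to 13827 of 19983 protein-coding genes (69.2%). With a q-value of 1e-10 or less required, 10288 L1 peaks were left, and with a fold enrichment of 3 or more, 29.

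In L2, the strongest peak lay in the promoter of the F-box gene fbxb-72 (chromosome V, 724647 to 727103), with a fold enrichment of 2.25. F19G12.12 (2.1) and Y5H2A.4 (2.06), both among the top 10 genes of L1, were also among the top 10 of L2. The others were T19D12.1 (2.08), K02F3.13 (2.04), the ABC transporter gene wht-8 (2.04), and slc-17.6, T07D3.4, F01D5.10 and R10E11.13 at 2.00 each. The slc-17.6 peak lay in exon 7 of lgc-51 and the R10E11.13 peak in exon 8 of cbp-1. The L2 list held 8336 peaks with a median width of 248 bp, which covered 2.42 Mb, with a median fold enrichment of 1.54. Promoters within 1 kb held 49.4% of annotated peaks (48.3 to 50.5), all promoter classes 86.9% and exons 9.19%. Peaks were assigned to 4904 protein-coding genes (24.5%). Only 30 L2 peaks had a q-value of 1e-10 or less, and none reached a fold enrichment of 3.

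The next comparison asked whether the L2 sites were a part of the L1 sites. Of 8334 L2 peaks on the nuclear chromosomes, 8152 (97.8%, 95% Wilson interval 97.5 to 98.1) overlapped an L1 peak, against 23.5% ± 0.483 (SD over 100 shuffles) by chance. The shuffles placed peaks anywhere along a chromosome. That chance value therefore leaves out overlap that arises because both lists lie near transcript starts or share high-background DNA. Conversely, 7744 of 37019 L1 peaks (20.9%, 20.5 to 21.3) overlapped an L2 peak. Genes with a peak in both stages numbered 6118, which is 97.9% of the genes with an L2 peak. The 182 L2 peaks outside L1 peaks were weak, with a fold enrichment of at most 1.72. Those with the highest values, singled out after the values were seen, lay at the non-coding T13H10.10 (1.72), the autophagy gene atg-10 (1.71) and F15B10.3 (1.71). The share of L1 peaks that overlapped an L2 peak rose with L1 enrichment, from 5.06% in the lowest of 5 equal bins to 52.9% in the highest. The lists differ in length, and the share of L2 peaks in an L1 peak was 55.8% when the L1 list was limited to its 8334 peaks of highest score. A reciprocal overlap of 50% gave 59.4%.

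**Figure D1:**
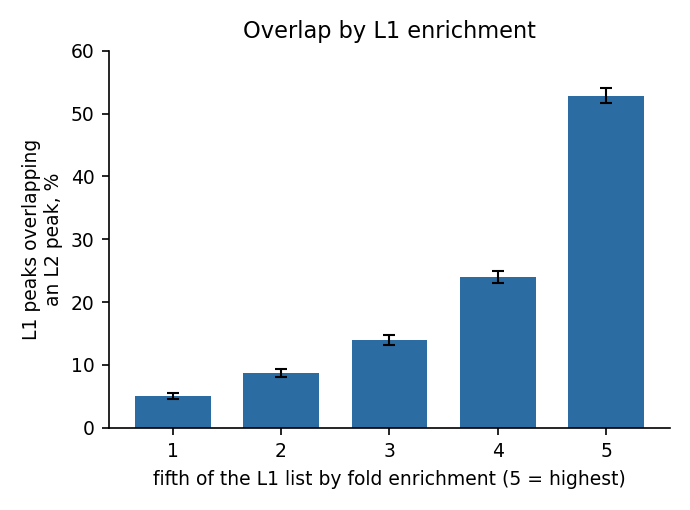
Share of L1 peaks that overlap an L2 peak by at least 1 bp (vertical axis, percent) in 5 equal bins of the L1 list by fold enrichment (horizontal axis, 5 is the highest); error bars are 95% Wilson intervals. The share is 5.06% in the lowest bin and 52.9% in the highest.

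The comparison of occupancy between the stages asked which sites gained or lost LIN-14 from L1 to L2. In the authors' deposited table, 6082 sites had lower occupancy in L2 at an FDR below 0.05 and 18 had higher occupancy. The lowered sites with the lowest FDR in the authors' deposited table included the promoters of bcmo-1 (log2 fold -0.96, FDR 0.00387; chromosome II, 12830700 to 12831165) and C36H8.1 (-0.92). Others of that group in the authors' deposited table were exon 2 of nep-3, a neprilysin-type peptidase (-1.04, FDR 0.00402; chromosome II, 3873894 to 3874140), and promoter sites of grl-15, a hedgehog-related gene (-0.99), npp-25, a nuclear pore gene (-0.99), and K10B4.3 (-0.93). The piRNA gene 21ur-1163 (-0.92), T22F7.5 (-0.93) and the non-coding T28D6.14 (-0.95) were also in that group in the authors' deposited table. All of these sites overlapped an L1 peak and 0 overlapped an L2 peak.

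Among the listed sites, nearly all shared the drop, which was small. Of 14675 sites listed in the authors' deposited table, 14638 (99.7%) had a log2 fold below 0 and 37 had one above 0. The median log2 fold in the authors' deposited table was -0.44 (interquartile range -0.55 to -0.35), which is an occupancy lower by 26.3%. Lowered sites had a median of -0.57 in the authors' deposited table, and 21 of them reached -1 or below. Relative to the common median, the picture differed: tested against -0.44 in place of 0, with standard errors from the authors' deposited table (median 0.20), 0 sites lay below it after adjustment (88 at an unadjusted p under 0.05) and 29 lay above it. The SD of the log2 folds over listed sites in the authors' deposited table was 0.15, less than the median standard error. At an unadjusted p under 0.05, 0.6% of listed sites lay below the median and 0.252% above. The share below was smaller than chance alone would give, though the missing sites also shift the median. The cut at an FDR of 0.3 left no listed site with a log2 fold between -0.175 and 0.175. The share above was limited by that cut and cannot be set against chance. The standard errors may be too wide for this test, but an SD and shares from a cut list cannot settle that. The test had little power for small departures in simulated data, so 0 sites below does not show that no site fell more than the rest. The table lists no site with an FDR above 0.3, so about 2227 tested sites are missing from these shares, from the median and SD and from the test against the median, and the normalization behind the folds is not given in the sources used here.

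**Figure D2:**
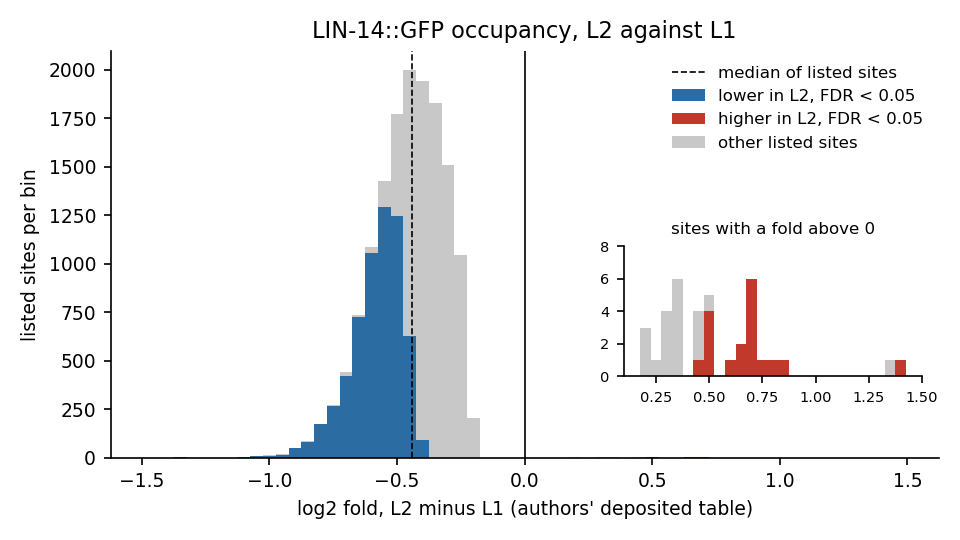
Log2 fold in occupancy, L2 minus L1, from the authors' deposited table (horizontal axis) against the number of listed sites per bin of 0.05 (vertical axis), with lowered sites in blue, raised sites in red and other listed sites in grey; the inset enlarges the sites above 0. The dashed line is the median, -0.44, and 14638 of 14675 sites lie below 0.

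The sites with higher occupancy in L2 were few. The largest rise in the authors' deposited table was at Y70G10A.4 (log2 fold 1.41, FDR 0.00713; chromosome III, 10224522 to 10224780), where the log2 concentration was 5.64 in L1 and 7.05 in L2. A site upstream of lgc-26, a gene of the ligand-gated ion channel family (chromosome V, 264963 to 265977), rose by 0.82 in the authors' deposited table (FDR 0.00856) from an already high log2 concentration of 9.80. Further raised sites in the authors' deposited table were assigned to gtnt-50 (0.72), Y20C6A.4 (0.71), the microRNA gene mir-249 (0.64), the calponin gene cpn-3 (0.70) and tbb-4, a beta-tubulin of ciliated sensory neurons (0.68). The ribosomal RNA gene rrn-4.2 (0.73), Y57E12B.4 (0.70) and the chemoreceptor gene str-221 (0.69) completed the first 10 genes with a raised site in the authors' deposited table. A second raised site was listed in the authors' deposited table for lgc-26 (0.84) and for Y70G10A.4 (0.52), and a site 876 bp past the start of lgc-26 was lowered (-0.78, FDR 0.00939; chromosome V, 269115 to 269413). Of the 18 raised sites, 7 overlapped an L1 peak and 4 an L2 peak, whereas of the 6082 lowered sites 6076 overlapped an L1 peak and 2147 an L2 peak. Of the 18, 2 passed an FDR below 0.01 in the authors' deposited table. When direction was taken after subtracting the median, 173 changed sites counted as higher and 5824 as lower. That recount kept the calls made against 0, so the 173 include lowered sites whose drop was smaller than the median. It is not a test for a rise.

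Heterochronic genes, which order the larval cell fates, were examined by name. The let-7 microRNA gene had 1 L1 peak and no L2 peak, and occupancy within 1 kb of its start fell by 0.63 in the authors' deposited table (FDR 0.0176; chromosome X, 14743651 to 14743985). All 3 listed sites of lin-41, a let-7 target that encodes a TRIM-NHL protein, were lowered in the authors' deposited table, by a log2 fold of -0.63 within 1 kb of its start (chromosome I, 9340868 to 9341608), -0.61 and -0.51. At hbl-1, a hunchback-type zinc finger gene with 3 peaks in each stage, 1 of 2 listed sites was lowered in the authors' deposited table (-0.49, FDR 0.0262) and the other was not (-0.29, FDR 0.20). The single listed site of lin-14 itself did not pass in the authors' deposited table (-0.27, FDR 0.222; chromosome X, 11482049 to 11482342), nor did the 4 sites of lin-29, whose log2 folds ran from -0.50 to -0.28, or the site of lin-42 (-0.49, FDR 0.0768). Assigned peaks numbered 4 in L1 and 1 in L2 for lin-14, 7 and 2 for lin-29, and 7 and 0 for lin-42. The single lin-42 site leaves most of its L1 peaks without a listed fold. L1 peaks without a listed site were assigned to lin-46 (1 peak), daf-12 (2) and mab-10 (2), and no peak of either stage was assigned to lin-4 or lin-28. Among genes of neuronal maturation, nlp-45, a neuropeptide gene, had 1 L1 peak at its start and a lowered site in the authors' deposited table (-0.53, FDR 0.0318; chromosome X, 2337918 to 2338362). The homeobox gene unc-30, needed for GABA neuron identity, had 5 L1 peaks and 1 L2 peak, and its 2 listed sites did not pass in the authors' deposited table (-0.48, FDR 0.0541, and -0.39, FDR 0.0664). The insulin-like gene ins-33 had 2 L1 peaks and oig-1, an immunoglobulin-domain gene, had 1, with no listed site, and irx-1 had no assigned peak.

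Of the 24 heterochronic list members, 16 had a listed site. At 1 site per gene, 10 were lowered in the authors' deposited table, the same number as when adjusted over the list alone. These 10 in the authors' deposited table were lin-66 (-0.82), alg-2 (-0.74), kin-20 (-0.73), ain-1 (-0.72), nhl-2 (-0.71), sea-2 (-0.70), let-7 (-0.63), lin-41 (-0.63), puf-9 (-0.61) and dre-1 (-0.58). The share, 62.5% against 42% of other genes with a site in the authors' deposited table, did not pass Fisher's exact test over 23 lists (adjusted p = 0.734). The size of the drop did set the list apart: its median log2 fold in the authors' deposited table was -0.62, against -0.44 in gene sets matched on concentration (permutation p = 0.0001, the smallest that 10000 permutations can give; adjusted p = 0.0023). No other list passed that test after adjustment, with hedgehog-related genes (-0.52, permutation p = 0.0169) and collagens (-0.49, permutation p = 0.0201) nearest in the authors' deposited table, both at an adjusted p of 0.154. Of the 16 members, lin-14, hbl-1, blmp-1, alg-1 and lin-29 had log2 folds of -0.27 to -0.39 in the authors' deposited table, less negative than the common median.

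**Figure D3:**
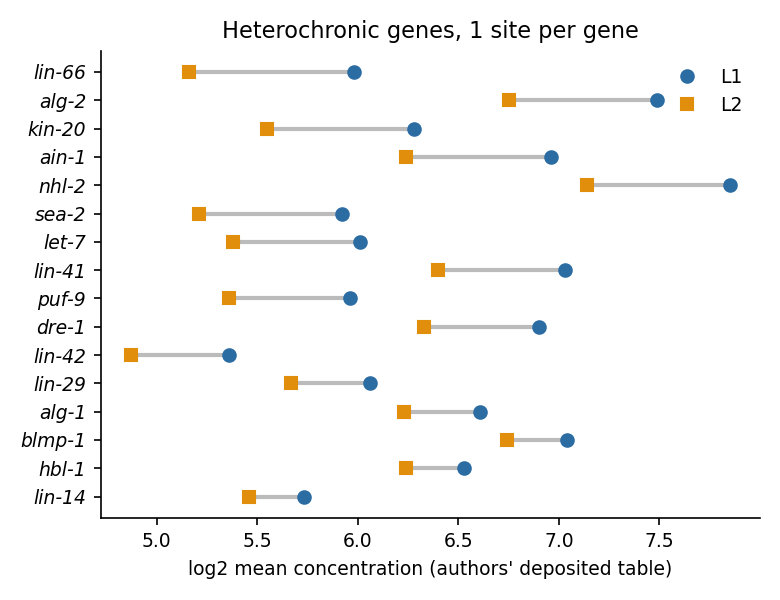
Log2 mean concentration (horizontal axis, authors' deposited table) in L1 (circles) and L2 (squares) at the site of highest concentration of each of 16 heterochronic genes. All 16 values are lower in L2, by -0.82 at lin-66 to -0.27 at lin-14, and 10 of the 16 sites pass an FDR below 0.05.

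Neuronal gene lists were examined in the same way. Counts use 1 site per gene, while the examples give the member's site of lowest FDR, which need not be the site counted. Counts adjusted over the list alone rest on listed sites only and can be too high. Among neuropeptide genes, 3 of 12 FLP genes with a listed site were lowered in the authors' deposited table (3 adjusted over the list alone), with flp-28 at -0.63, flp-12 at -0.58 and flp-34 at -0.58. In the NLP group, 13 of 29 were lowered in the authors' deposited table (24 adjusted over the list alone), with nlp-25 at -0.70, nlp-61 at -0.62 and nlp-7 at -0.57. Of 7 insulin-like genes, ins-5 (-0.50) and ins-1 (-0.47) were lowered in the authors' deposited table (6 adjusted over the list alone). Among neuropeptide receptors, 18 of 41 were lowered in the authors' deposited table (21 adjusted over the list alone), including frpr-3 (-0.70), npr-37 (-0.69) and npr-42 (-0.68). Neurotransmitter receptors had 18 of 45 lowered and 1, the lgc-26 site above, raised in the authors' deposited table (25 and 1 adjusted over the list alone), with lgc-47 at -0.83 and lgc-45 at -0.82. Of these receptor examples, the lgc-47 site lay in exon 5 of dpy-22 and the npr-42 site in intron 2 of Y71H2AL.3. Chemoreceptors had 170 of 443 lowered and 1, str-221, raised in the authors' deposited table (171 and 1 adjusted over the list alone), with srh-159 at -0.93, srab-16 at -0.86 and srh-37 at -0.80. Transmitter identity genes had 7 of 10 lowered in the authors' deposited table (7 adjusted over the list alone), among them the monoamine synthesis genes bas-1 (-0.56) and cat-2 (-0.59) and the acetylcholine synthesis gene cha-1 (-0.54). Synaptic genes had 7 of 16 lowered in the authors' deposited table (11 adjusted over the list alone), with syd-2 at -0.87 and egl-3 at -0.84. Adhesion and guidance genes had 16 of 34 lowered in the authors' deposited table (19 adjusted over the list alone), with plx-1 at -0.82 and rig-1 at -0.77. Members with the highest concentration of their list did not all pass in the authors' deposited table, as at nlp-66 (-0.38, FDR 0.0741), casy-1 (-0.22, FDR 0.229) and a second site of cla-1 (-0.37, FDR 0.101). None of these lists passed Fisher's exact test for its lowered share, with adjusted p from 0.734 to 1 on the authors' deposited table. Apart from the chemoreceptors, they held 7 to 45 genes, fewer than any list tried on simulated data. A difference could therefore be missed, as at 70% of transmitter identity genes or 25% of FLP genes against 42% of other genes in the authors' deposited table.

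Regulators, cuticle and signalling genes came next. Of 45 homeobox genes 21 were lowered in the authors' deposited table (22 adjusted over the list alone), with hmbx-1 at -0.98, and of 107 nuclear hormone receptors 40 were (42 adjusted over the list alone), with nhr-155 at -0.83. Collagens, the main proteins of the cuticle, were lowered most often among the lists with more than 16 genes in the authors' deposited table, at 47 of 82 genes or 57.3% (60 adjusted over the list alone), with col-36 at -0.87, col-129 at -0.81 and col-103 at -0.78. That excess over the 41.9% of other genes in the authors' deposited table failed the correction (Fisher's exact p = 0.00667, adjusted p = 0.153). Hedgehog-related genes had 15 of 28 lowered in the authors' deposited table (18 adjusted over the list alone), with grl-16 at -0.86 and grl-19 at -0.70, and molting genes 20 of 58 (32 adjusted over the list alone), with nas-32 at -0.78 and noah-1 at -0.72. Wnt pathway genes had 5 of 10 lowered in the authors' deposited table (8 adjusted over the list alone), among them the Wnt ligand gene lin-44 (-0.64) and the Frizzled receptor gene lin-17 (-0.72). Dauer and insulin pathway genes had 6 of 15 lowered in the authors' deposited table (6 adjusted over the list alone), including daf-8 (-0.68) and the insulin receptor gene daf-2 (-0.71 and -0.53 at different sites). Cell cycle genes had 8 of 17 (8 adjusted over the list alone), with mcm-2 at -0.66 in the authors' deposited table. For ribosomal protein genes the count was 4 of 8 in the authors' deposited table (7 adjusted over the list alone), and for histone genes 1 of 6 (0 adjusted over the list alone). Markers of other tissues had 4 of 15 muscle genes (9 adjusted over the list alone), 7 of 15 intestine genes (11) and 7 of 19 germline genes (8) lowered in the authors' deposited table, with unc-89 at -0.76, mtl-1 at -0.76 and mex-3 at -0.85. The members of highest concentration did not pass in the authors' deposited table at ceh-23 (-0.36, FDR 0.0692), col-81 (-0.28, FDR 0.153), wrt-6 (-0.40, FDR 0.0987), cpr-1 (-0.39, FDR 0.0512) and ttn-1 (-0.46, FDR 0.0528). Those of the other lists in this paragraph were lowered in the authors' deposited table, as at nhr-270 (-0.54, FDR 0.026), apr-1 (-0.59, FDR 0.016) and prg-1 (-0.58, FDR 0.0239). No list passed in the lowered or the raised direction in Fisher's exact test over 23 lists on the authors' deposited table (0 lists; 1 list, the collagens, at an unadjusted p under 0.05).

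**Figure D4:**
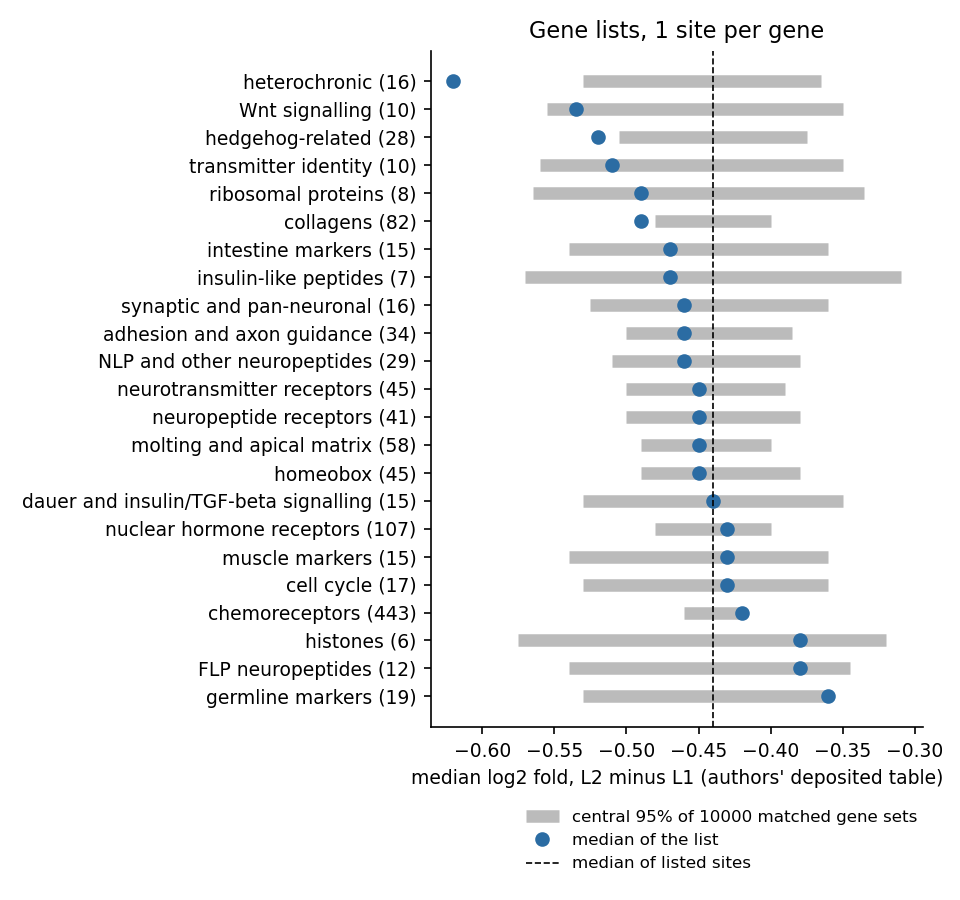
Median log2 fold, L2 minus L1, from the authors' deposited table (horizontal axis) for each of 23 gene lists, with the number of genes with a listed site in parentheses; points are list medians and grey bars the central 95% of 10000 gene sets matched on concentration. The heterochronic (-0.62), hedgehog-related (-0.52) and collagen (-0.49) medians lie below their bars, the last 2 without passing the correction, and the dashed line is the median of listed sites, -0.44.

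Which gene groups carried LIN-14 peaks was tested next. Genes of molting and the apical matrix had an L1 peak in 88 of 98 protein-coding members (89.8%, against 69.1% of other protein-coding genes; Fisher's exact test, adjusted p = 1.26e-05) and an L2 peak in 44 (44.9% against 24.4%, adjusted p = 0.000114). By Fisher's exact test, histone genes had an assigned peak less often than other protein-coding genes, at 15 of 72 in L1 (20.8%, adjusted p = 7.4e-16) and 1 of 72 in L2 (1.39%, adjusted p = 1.24e-06). Ribosomal protein genes were also low by Fisher's exact test, at 23 of 75 in L1 (30.7%, adjusted p = 9.35e-11) and 8 of 75 in L2 (10.7%, adjusted p = 0.0331). Each peak was assigned only to its nearest transcript, and gene length, gene spacing and repeated sequence were not taken into account for any list. By the same Fisher's exact test, intestine markers had a peak in 22 of 24 genes in L1 (adjusted p = 0.0549) and in 12 of 24 in L2 (50%, adjusted p = 0.0418). The heterochronic genes did not pass Fisher's exact test among protein-coding genes, at 18 of 19 in L1 (adjusted p = 0.0549) and 10 of 19 in L2 (adjusted p = 0.0573).

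Set against all annotated genes, which include many non-coding genes, 22 of 23 lists passed in L1 and 19 in L2. Among them, 901 of 1629 chemoreceptor genes (55.3% against 39.1% of others), 68.6% of 287 nuclear hormone receptors, 131 of 181 collagens (72.4%) and 19 of 20 Wnt pathway genes (95%) had an L1 peak. In Fisher's exact test, histones were the only list of the 22 that passed with a lower share than other genes (20.8% against 39.7%, adjusted p = 0.0012), and ribosomal proteins did not pass (adjusted p = 0.125). With the background limited to protein-coding genes, 3 lists passed in L1 and 4 in L2. The chemoreceptors, nuclear hormone receptors, collagens and Wnt pathway genes were not among them in either stage. In L1, 68.7% of protein-coding chemoreceptors had a peak against 69.2% of others, and 95% of Wnt pathway genes against 69.2% (Fisher's exact test, adjusted p = 0.0549).

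The last comparisons asked whether changed sites lay in particular classes or chromosomes. Promoter sites were changed slightly less often than the rest in the authors' deposited table, at 5257 of 12841 (40.9%) against 843 of 1834 (46%; odds ratio 0.815, Fisher's exact p = 5.03e-05). Exon sites had a changed share of 47.3% and intron sites 46.6% in the authors' deposited table. At an FDR below 0.01 the difference between promoters and other classes no longer passed (odds ratio 0.942, Fisher's exact p = 0.709). X-linked sites were changed less often than autosomal sites in the authors' deposited table, at 928 of 2510 (37.0%) against 5172 of 12165 (42.5%; odds ratio 0.793, Fisher's exact p = 2.74e-07). Median log2 folds in the authors' deposited table differed little, at -0.43 on X and -0.45 on autosomes, and at -0.44 in promoters and -0.47 elsewhere.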

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

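The mitochondrial chromosome, which the authors' annotated lists and the comparisons above leave out, held 11 peaks in the L1 list. They covered 8406 bp, with fold enrichments from 1.51 to 2.05. The L2 list had 2 mitochondrial peaks covering 13150 bp, both with a fold enrichment of 1.4. No biological explanation was tested.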

How the results depend on the processing

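The tests against the median fold, the limit to sites in a peak of either stage, and the heterochronic alternatives were chosen after the data were seen. Merging peaks within 200 bp kept both peak counts within 1.5 times. A q-value of 1e-10 or less left 10288 L1 and 30 L2 peaks, and a fold enrichment of 3 or more left 29 and 0. The share of L2 peaks in an L1 peak was 59.4% with a reciprocal overlap of 50%, 83.5% with centres within 200 bp, 55.8% with equal list lengths and 100% for the 30 L2 peaks of stricter q. In the authors' deposited table, lowered and raised sites numbered 264 and 2 at an FDR below 0.01, 21 and 1 with an absolute log2 fold of at least 1, and 2147 and 4 in a peak of both stages. Tested against the median in place of 0, with standard errors that may be too wide for that test, 0 were lower and 29 higher. Further, 9962 were lowered at an FDR below 0.1, 3332 were lowered above the median concentration, and 7 raised sites lay in a peak of either stage. After subtracting the median, with calls still made against 0, 173 counted as higher. The promoter odds ratio was 0.942 at an FDR below 0.01, and the X chromosome difference passed under both alternatives. Lists with a peak share apart from other genes numbered 8 in L1 and 7 in L2 for the top 2000 peaks, 3 and 4 among protein-coding genes, and 11 in L2 for peaks within 1000 bp. Changed lists stayed at 0 under 4 alternatives and reached 1 by the permutation test. Of 118 named sites, 91 no longer passed when tested against the median and 27 kept their side of the threshold. The smaller counts follow from the stricter filters; for the other differences the cause was not tested. No paired analysis was possible because the lists and the table hold no values per library; leaving out or regrouping libraries and the motif search were not run for want of such values and of a genome.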

Other observations

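The test of exon and intron sites, the reading of the heterochronic result against concentration, the tests of read density and of matched sites for raised sites and the use of an interval for their L2 share were chosen after the results were seen. The genes with the most LIN-14 peaks were named after their values were seen, and gene length was not taken into account. In L1, dig-1 had 29 peaks, unc-52, which encodes perlecan, 28, fln-2 and rin-1 18 each, tir-1 17, him-4, which encodes hemicentin, 16, and gap-2 and let-805 15 each. In L2, the non-coding ZK617.21 had 11 peaks, and him-4, mup-4 and fig-1 had 9 each. Non-coding RNA genes of the broad class took 14.4% of L1 peaks, piRNA genes 4.19% and microRNA genes 0.581%, and in L2 13.6%, 4.19% and 0.708%. Exon and intron sites together were changed in 47.2% of cases against 40.9% elsewhere in the authors' deposited table (Fisher's exact p = 5.01e-06).

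The highest concentration in the authors' deposited table was at the ribosomal RNA gene rrn-2.1 (chromosome I, 15063995 to 15067645), at a log2 value of 14.63, with a log2 fold of -0.25 (FDR 0.224). Second was the raised site upstream of lgc-26, at 10.27 in the authors' deposited table. The 42 listed sites in no peak of either stage included C36E6.8, with the lowest log2 fold in the authors' deposited table (-1.43, FDR 0.0276), and rrn-1.1 (1.36, FDR 0.0617).

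Nearly all listed sites had a lower occupancy in L2, which one scaling factor between the stages could give as well as loss of LIN-14. If only the signal at sites had dropped over an unchanged background, the most enriched sites should fall most. By L1 enrichment, the top of 5 equal bins of sites had a median log2 fold differing by -0.13 from the bottom bin (95% bootstrap interval -0.15 to -0.13) in the authors' deposited table. By L2 enrichment the difference was -0.05 (-0.06 to -0.03) in the authors' deposited table, which does not pass the limit of 0.05 set beforehand, and what sorting on a stage's own signal adds to either value was not tested. A common factor and a loss of LIN-14, whose known fall after L1 was not measured here, cannot be told apart, since the normalization is not given in the sources used here and values per library were not used here.

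The 18 raised sites may lie in repeated or high-background DNA. A peak of either stage overlapped 38.9% of them, against 99.9% of lowered sites (Fisher's exact p = 3.62e-26). Against other sites of similar concentration in the authors' deposited table, 38.9% lay in an L1 peak where 98.9% did of sites matched in L1, and 22.2% in an L2 peak where 87% did of sites matched in L2 (permutation p = 0.0001 each, the smallest that 10000 sets can give). Median read density in the authors' deposited table was 327 normalised reads per kb against 153 at lowered sites (permutation p = 2e-05, the smallest that 100000 permutations can give). A gain of LIN-14 at some of these sites stays open: 22.2% is below the limit of 25% set beforehand for arguing against it, but the 95% Wilson interval, brought in after that value was seen, ran from 9 to 45.2.

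The heterochronic genes had a more negative median log2 fold than gene sets matched on concentration, by -0.18 (permutation p = 0.0001) in the authors' deposited table, and concentration could not give that: among other genes the lowest median in any of 20 concentration bins was -0.48, against -0.62 in the list. The choice of site was tested with the site nearest to the transcript start, which left -0.145 (permutation p = 0.0009) in the authors' deposited table. Matching on the enrichment of the overlapping L1 peak left -0.165 (permutation p = 0.0004) in the authors' deposited table. Without any 1 of the 16 members the difference stayed between -0.19 and -0.17. Leaving out 1 member can only move the list median to a middle value, here -0.63 (lin-41) or -0.61 (puf-9) in the authors' deposited table. That narrow range was therefore set beforehand and does not show that the result is free of single members. A hypothesis, which counts per library of an independent L1 and L2 series would test, is that LIN-14 leaves a part of the genes of its own timing pathway to a larger extent than others. It was found and tested on the same folds, 5 of 16 members, lin-14 and hbl-1 among them, had values less negative than the common median, and the list did not stand apart in its count of lowered genes (Fisher's exact test, adjusted p = 0.734).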
